A study of Arabidopsis thaliana with 8 samples.

How the data were processed

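Each deposited file lists distinct small RNA sequences with the number of reads of each, and these raw read counts per sequence, as the authors deposited them, were the values analysed. Per the labels, RNA came from inflorescences of long-day plants grown at 22 °C, the 15- to 40-nt fraction was cut from a gel, libraries were made with an Illumina small RNA kit, and the 4 genotypes were barcoded and run in a single HiSeq2000 channel, with 2 biological replicates per genotype. The n of each group is therefore 2 biological replicates, and p-values compare genotypes over such replicates. The adapter trimming of the authors, and any aligner or genome build they used, are not given in the sources used here. Files hold sequences of 18 to 42 nt. Reads of up to 40 nt were counted in the library size, and reads with an undetermined base were left out of all matching.

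Sequences were matched exactly, on both strands, to the TAIR10.1 genome and its annotation with Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3), and figures were drawn with matplotlib 3.10.9. Matched reads were assigned to classes by annotated feature. The 45S repeat is not fully annotated, so the rRNA class took in 4000 bp after each 5.8S gene. The annotation used has no transposon class, so transposons were not counted as such.

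From general knowledge of Arabidopsis miRNAs, a list of 124 mature small RNAs (118 miRNAs and 6 ta-siRNAs) was written before the data were examined. Of them, 117 matched annotated mature miRNAs. Sequences that cannot be told apart by their first 15 nt were joined into 110 groups. Of these, 15 had no full-length read in any library (8 of them had other reads) and were not analysed here, and 95 were kept. TAS genes had 0 or 1 reads per library. Such reads may be missing from the files used here, so their absence is not read as a result. A read belonged to a group if it shared the first 15 nt of the mature sequence. Its longest match to the mature sequence and 12 nt of genomic continuation was its templated part and the remainder its tail. Tails were sorted as U alone or as holding another base, and reads without a tail as full length, truncated or extended. Reads whose remainder was longer than 12 nt (0.313 to 1.76% of the reads of a library) were left out. So were reads whose remainder of 3 nt or more returned to the template after 1 base, as an internal substitution would (0.153 to 0.564%). Tails on other small RNAs were taken from reads of up to 32 nt with a longest genome-matching prefix of 18 nt or more and a tail of up to 8 nt.

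miRNA abundance was tested with edgeR 4.0.16 in R 4.3.3. The fit was quasi-likelihood over all 8 libraries (4 residual degrees of freedom), with the library size set to all reads of 15 to 40 nt, no further scaling and filterByExpr. Shares were tested with the same tool as the reads of a form against the remaining reads of the group, which gives a log2 odds ratio, for groups with 50 or more reads in each library. The mean U-tail length was tested with limma 3.58.1 for groups with 20 or more U-tailed reads in each of 4 libraries. Single-match 24-nt reads were counted in windows of 500 bp and tested as abundance was. P-values were adjusted by Benjamini-Hochberg over the groups or windows of a comparison, and a change was called under 0.05. The contrasts were hen1-8 against wild type, the double mutant against hen1-8, heso1-1 against wild type, and the interaction of HESO1 loss with the hen1-8 background. No test was run on size and siRNA tail profiles, which are given as library values. The splits of the U-tailed share by tail length and by full-length or truncated prefix were added after the data were seen. Alternatives used DESeq2 1.42.0, limma on log2 odds, TMM factors, the replicate number as a block, other read thresholds and other definitions of tail and truncation.

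The lists were developmental regulators conserved in flowering plants (23 groups listed), nutrient regulators (11), regulators of the small RNA pathway (3), ta-siRNA triggers (3), narrowly conserved miRNAs (66), miRNAs longer than 21 nt (22), miRNAs with a 5′ base other than U (19) and ta-siRNAs (5, not analysed here). They were tested with fry, whose directional p-value asks whether members move on balance one way and whose mixed p-value asks whether they change in either direction. Neither compares a list with other groups. camera with an estimated correlation between members was the alternative, and it does compare a list with other groups. The miRNAs named in every comparison where they passed were fixed before the data were examined: miR156 to miR160, miR161.1, miR162 to miR169, miR171a, miR172, miR173, miR319, miR390, miR393, miR394, miR396, miR398, miR403 and miR408, as groups sharing their first 15 nt. To these the rule adds the 3 largest rises and the 3 largest falls of each comparison among called groups, or windows, whose libraries do not overlap between the genotypes. Other called groups named in the text, such as miR161.2, miR171b, miR447a, miR827, miR858a, miR867 and miR780.1 where they are not among these, were chosen after their values were seen.

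Fold changes against a group with 0 reads used a floor of 3 counts over the group, and shares of 0 the upper 95% counting limit. Each analysis was also repeated with 1 library left out at a time. A genotype then has a single library and the spread comes from the other genotypes, so a call lost this way does not by itself show that the effect was lost.

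The tests were tested on simulated data, in 20 draws per comparison and 1 for windows, with known 2-fold and 4-fold changes. The abundance test found 18.2% of the 2-fold and 73.8% of the 4-fold changes, and the window test 21.9 and 73.5%. The U-tailed share test found 42.5 and 81.3% with a fixed spread between replicates (intraclass correlation 0.005) and 63.3 and 92.5% with the spread measured in the replicates. The truncated share test found 38.3 and 82.5% with the fixed spread and 56.7 and 88.8% with the measured spread, and the test of other tails 15.0 and 61.3%, and 35.8 and 80.0%. The tail length test found 84.0% of shifts of 0.5 nt and 91.0% of shifts of 1 nt. False calls made up 6.91% of abundance calls, 2.11% of window calls, 3.31% of length calls and 11.1% of truncated share calls with the fixed spread. The first form of this check used a single draw at the fixed spread, in which the test of other tails found none of its changed groups. Draws at that setting varied too much to judge, and the check was replaced by repeated draws at both spreads. A change under 4-fold that did not pass is thus often one the tests could not see.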

Results

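Small RNAs were sequenced from inflorescences of Arabidopsis thaliana (Col-0) of 4 genotypes, with 2 biological replicates per genotype and 8 libraries in all. The genotypes were wild type, heso1-1, hen1-8 and the hen1-8 heso1-1 double mutant. HEN1 is the methyltransferase that methylates the 3′-terminal ribose of plant miRNAs and siRNAs, and HESO1 is a nucleotidyltransferase that adds uridines to small RNA 3′ ends. The deposited files gave each distinct sequence of 18 to 42 nt with its read count. Replicates 1 and 2 held 10596021 and 7638946 reads in wild type, 7155825 and 13470428 in heso1-1, 10516489 and 23249325 in hen1-8, and 11932917 and 15341388 in the double mutant. The comparisons ask how small RNA 3′ ends differ when methylation is lost (hen1-8 against wild type), when HESO1 is lost in unmethylated plants (double mutant against hen1-8) and when HESO1 is lost in methylated plants (heso1-1 against wild type). Small RNA libraries do not measure the HEN1 and HESO1 mRNAs, so the mutated genes were not checked from these reads. Reads with an undetermined base made up 0.181 to 0.260% of the replicate 1 libraries and 0.0236 to 0.0256% of the replicate 2 libraries, which divides every genotype into 1 library of each kind. Values of replicate 1 and replicate 2 are therefore given, in that order, beside the main profiles. Values are means ± SD of 2 libraries (n = 2) unless stated. No molecular identifiers were used, so counting intervals and floors cover counting error only.

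Reads of 24 nt, the size of RNA-directed DNA methylation siRNAs, made up 54.2% ± 1.94 (SD, n = 2) of wild-type reads, 52.8% ± 1.28 in heso1-1, 34.1% ± 0.394 in hen1-8 and 32.3% ± 0.965 in the double mutant. Reads of 25 to 28 nt made up 4.32% ± 0.410 in wild type, 3.65% ± 0.309 in heso1-1, 18.8% ± 0.0653 in hen1-8 and 6.47% ± 0.150 in the double mutant. The gap between hen1-8 and each other genotype in this longer class was far larger than the spread between replicates, with library values of 4.03 and 4.61% in wild type, 3.86 and 3.43% in heso1-1, 18.7 and 18.8% in hen1-8 and 6.36 and 6.58% in the double mutant. The 24-nt shares of the libraries were 55.6 and 52.9%, 51.9 and 53.7%, 33.8 and 34.4%, and 31.6 and 33% in the same order. Reads of 20 to 22 nt, the size of most miRNAs, rose in share from 21.2% ± 0.912 in wild type and 24.1% ± 0.460 in hen1-8 to 32.7% ± 0.804 in the double mutant. Exact matches to the TAIR10.1 genome were found for 85.6 and 84.1% of wild-type reads, 85.3 and 85.4% of heso1-1 reads, 56.2 and 56.2% of hen1-8 reads, and 73.6 and 73.2% of double mutant reads. Reads from the chloroplast, a class of RNA not methylated by HEN1, made up 2.53% ± 0.0515 in wild type, 2.48% ± 0.319 in heso1-1, 0.899% ± 0.275 in hen1-8 and 0.797% ± 0.199 in the double mutant. Mitochondrial reads made up 1.24% ± 0.335, 1.13% ± 0.0286, 0.472% ± 0.0857 and 0.529% ± 0.0319. These profiles were not tested.

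**Figure D1:**
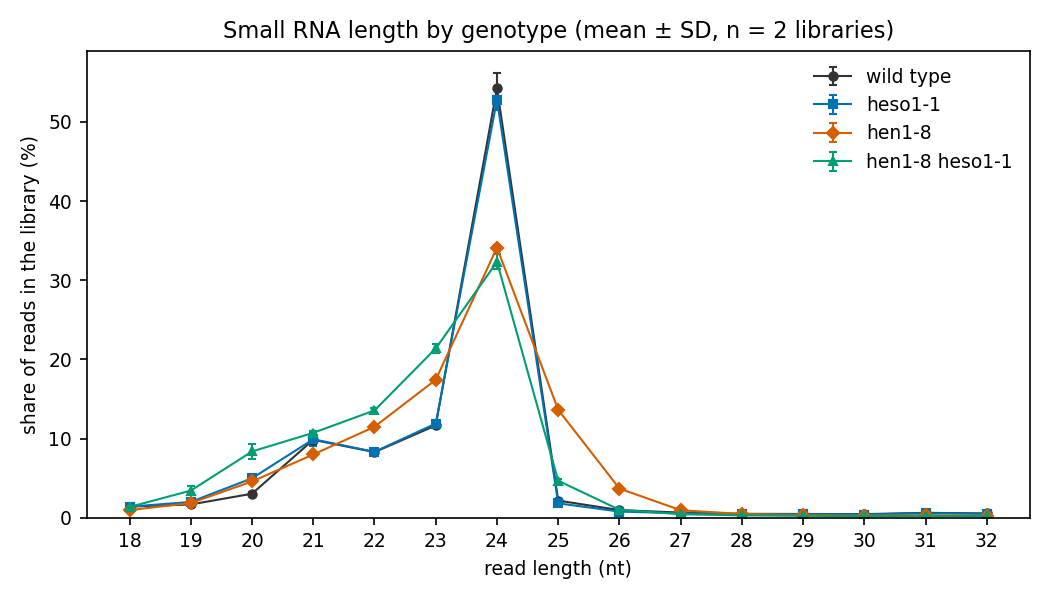
Share of all reads in a library (%) by read length (nt) in the 4 genotypes, as mean ± SD of 2 libraries. Wild type and heso1-1 peak at 24 nt (54.2 and 52.8%), and hen1-8 holds 18.8% of its reads at 25 to 28 nt.

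U tails on genome-matching prefixes of siRNA size were most common in hen1-8. Of reads whose longest genome-matching prefix was 24 nt, 20.3% ± 0.0694 (SD, n = 2) carried a tail of U alone in hen1-8, against 2.89% ± 0.0178 in the double mutant, 0.623% ± 0.0105 in wild type and 0.186% ± 0.0507 in heso1-1. For 23-nt prefixes the shares were 28.6% ± 0.485 in hen1-8, 2.95% ± 0.00226 in the double mutant, 5.89% ± 0.198 in wild type and 1.55% ± 0.218 in heso1-1. For 21-nt prefixes, which include many miRNAs, they were 23.4% ± 0.0835, 13.9% ± 0.148, 4.64% ± 0.598 and 1.88% ± 0.0789. The libraries of each genotype lay close together: at 24 nt they gave 20.3 and 20.4% in hen1-8, 2.88 and 2.90% in the double mutant, 0.616 and 0.631% in wild type, and 0.222 and 0.150% in heso1-1. When prefixes with a single genome match were used, the 21-nt value of wild type was 2.33% and that of heso1-1 was 2.27%. C tails behaved differently on 23-nt prefixes, with 13.7% ± 0.520 in hen1-8 and 19.5% ± 0.307 in the double mutant, against 2.38% in wild type and 2.36% in heso1-1. A tails on 24-nt prefixes made up 0.347% in wild type, 0.384% in heso1-1, 1.23% in hen1-8 and 3.83% in the double mutant.

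**Figure D2:**
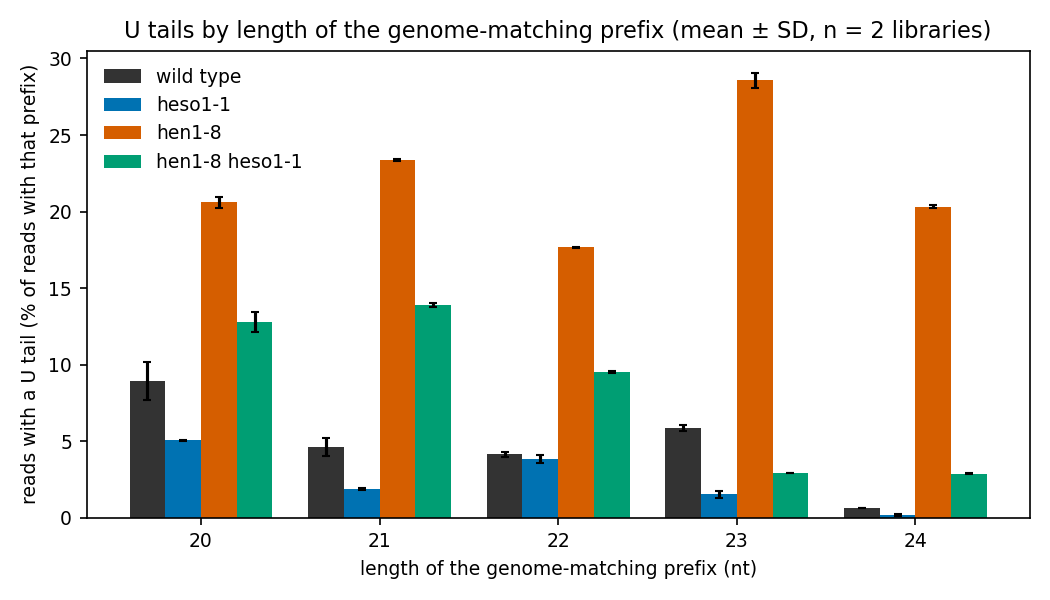
Share of reads with a tail of U alone (% of reads with that prefix) by length of the genome-matching prefix (nt) in the 4 genotypes, as mean ± SD of 2 libraries. At 24 nt the hen1-8 value is 20.3% and the double mutant value 2.89%, and at 21 nt they are 23.4 and 13.9%.

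Reads sharing the first 15 nt of a listed miRNA were then sorted by their 3′ end, and 38 miRNA groups had 50 or more reads in each of the 8 libraries. Over these groups, the median share with a tail of U alone was 5.03% ± 0.259 (SD, n = 2) in wild type, 2.99% ± 0.688 in heso1-1, 28.2% ± 2.48 in hen1-8 and 19.6% ± 2.77 in the double mutant (library values 5.22 and 4.85%, 3.48 and 2.51%, 26.4 and 29.9%, and 17.6 and 21.5%). Pooled over the reads of these groups it was 12.9% ± 2.28, 22.7% ± 0.258, 36.2% ± 1.01 and 28.4% ± 0.137 in that order, higher in heso1-1 than in wild type, and without miR158a 6.16, 2.28, 21.9 and 13.3%. The median share truncated by 1 nt or more with no tail was 4.52% ± 0.0711, 8.98% ± 0.342, 12.8% ± 0.0935 and 27.9% ± 2.05 (library values 4.47 and 4.57%, 8.74 and 9.22%, 12.7 and 12.9%, and 26.4 and 29.3%). The median share with a tail holding any other base was 3.35%, 1.95%, 11.6% and 3.10% (library values 4.17 and 2.53%, 2.56 and 1.34%, 12.6 and 10.5%, and 2.95 and 3.26%). The median share that was full length and untailed was 81.8%, 79.5%, 28.3% and 23.7%. Reads under 18 nt were not in the files, so truncation of an untailed 21-nt miRNA was seen to 3 nt at most, while tailed reads could be assigned by a templated part of 15 nt.

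In hen1-8 against wild type, the U-tailed share rose in 32 of the 38 miRNA groups and fell in 0 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The largest rise among developmental regulators was in miR159a/b/c, which targets GAMYB-like transcription factors, from 0.521% ± 0.0754 to 29.1% ± 2.18 (SD, n = 2; log2 odds ratio 6.29 ± 0.26 SE, adjusted p = 1.46e-12). Its miR159a locus lies on chromosome 1 at 27713234 to 27713254 (TAIR10.1), within the MIR159a gene AT1G73687. miR165a/miR166a, which targets class III HD-ZIP genes, rose from 0.322% ± 0.127 to 11.3% ± 0.893 (5.36 ± 0.39, adjusted p = 1.2e-09). miR396a/b, a regulator of growth-regulating factors, rose from 0.516% to 11.1% (4.61 ± 0.30, adjusted p = 3.72e-10), and miR171a, a regulator of GRAS family genes, from 0.892% to 17.8% (4.65 ± 0.47, adjusted p = 1.09e-07). Of the 14 developmental regulators tested, 11 rose (11 adjusted over the list alone). The others that passed were miR390a, miR167a/d, miR394a, miR160a, miR172a/c, miR157a and miR156h, with log2 odds ratios from 3.92 down to 1.23. miR319a/c, which targets TCP genes, stood at 28.8% ± 9.96 in wild type and 38% ± 4.04 in hen1-8 (0.63, adjusted p = 0.074), and miR393a at a log2 odds ratio of 0.48 (adjusted p = 0.078).

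The 3 regulators of the small RNA pathway all rose in U-tailed share. miR168a, which targets AGO1, went from 1.39% ± 0.410 to 20.2% ± 0.346 (4.20 ± 0.23, adjusted p = 3.7e-11). miR403, which targets AGO2, went from 2.03% ± 0.329 to 5.05% ± 1.10 (1.34 ± 0.25, adjusted p = 0.000125) and miR162a, which targets DCL1, from 4.76% ± 0.0803 to 7.46% ± 0.829 (0.69 ± 0.22, adjusted p = 0.00748; 0.103 without hen1-8 replicate 1). Both ta-siRNA triggers rose, miR173 from 8.41% ± 0.485 to 56.9% ± 4.97 (3.84 ± 0.45, adjusted p = 6.71e-07) and miR390a from 2.25% ± 1.10 to 25.6% ± 5.59 (3.92 ± 0.31, adjusted p = 4.14e-09). miR173 maps to chromosome 3 at 8236161 to 8236182, in the MIR173 gene AT3G23125. Of the 18 narrowly conserved miRNAs, 15 rose. They included miR161.1 (1.05% ± 0.305 to 25.4% ± 1.71, 4.98 ± 0.26), miR163 (6.30% ± 0.625 to 31.6% ± 0.213, 2.78 ± 0.20), miR158a (35.0% ± 2.58 to 53.6% ± 0.424, 1.10 ± 0.25), miR158b (1.08 ± 0.24) and miR824. miR824 had 0 U-tailed reads of 270 in wild type, which allows up to 1.11%, and 13.2% ± 2.49 in hen1-8 (adjusted p = 2.77e-05). Both nutrient regulators tested rose, miR827 (1.22 ± 0.43) and miR399b. miR399b had 0 U-tailed reads of 582 in wild type, which allows up to 0.515%, and 2.71% ± 1.06 in hen1-8 (adjusted p = 0.000809; 0.0636 without wild-type replicate 1 and 0.19 with tails of 2 nt or more). Of miRNAs longer than 21 nt, 5 of 6 rose, and of miRNAs with a 5′ base other than U, 4 of 5. Adjusted over each list alone, the counts were 3, 2, 15, 2, 5 and 4 in the order of these lists. By fry, which tests whether a list's members move on balance one way, every list rose (adjusted p from 4.45e-05 for developmental regulators to 0.00786 for nutrient regulators). With an estimated correlation, adjusted p = 0.783 for developmental, nutrient, ta-siRNA trigger and narrowly conserved miRNAs, 0.874 for small RNA pathway regulators and miRNAs with another 5′ base, and 0.952 for longer miRNAs. fry's mixed test did not pass the nutrient (0.263) and trigger (0.149) lists and passed the others (0.00296 or less).

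**Figure D3:**
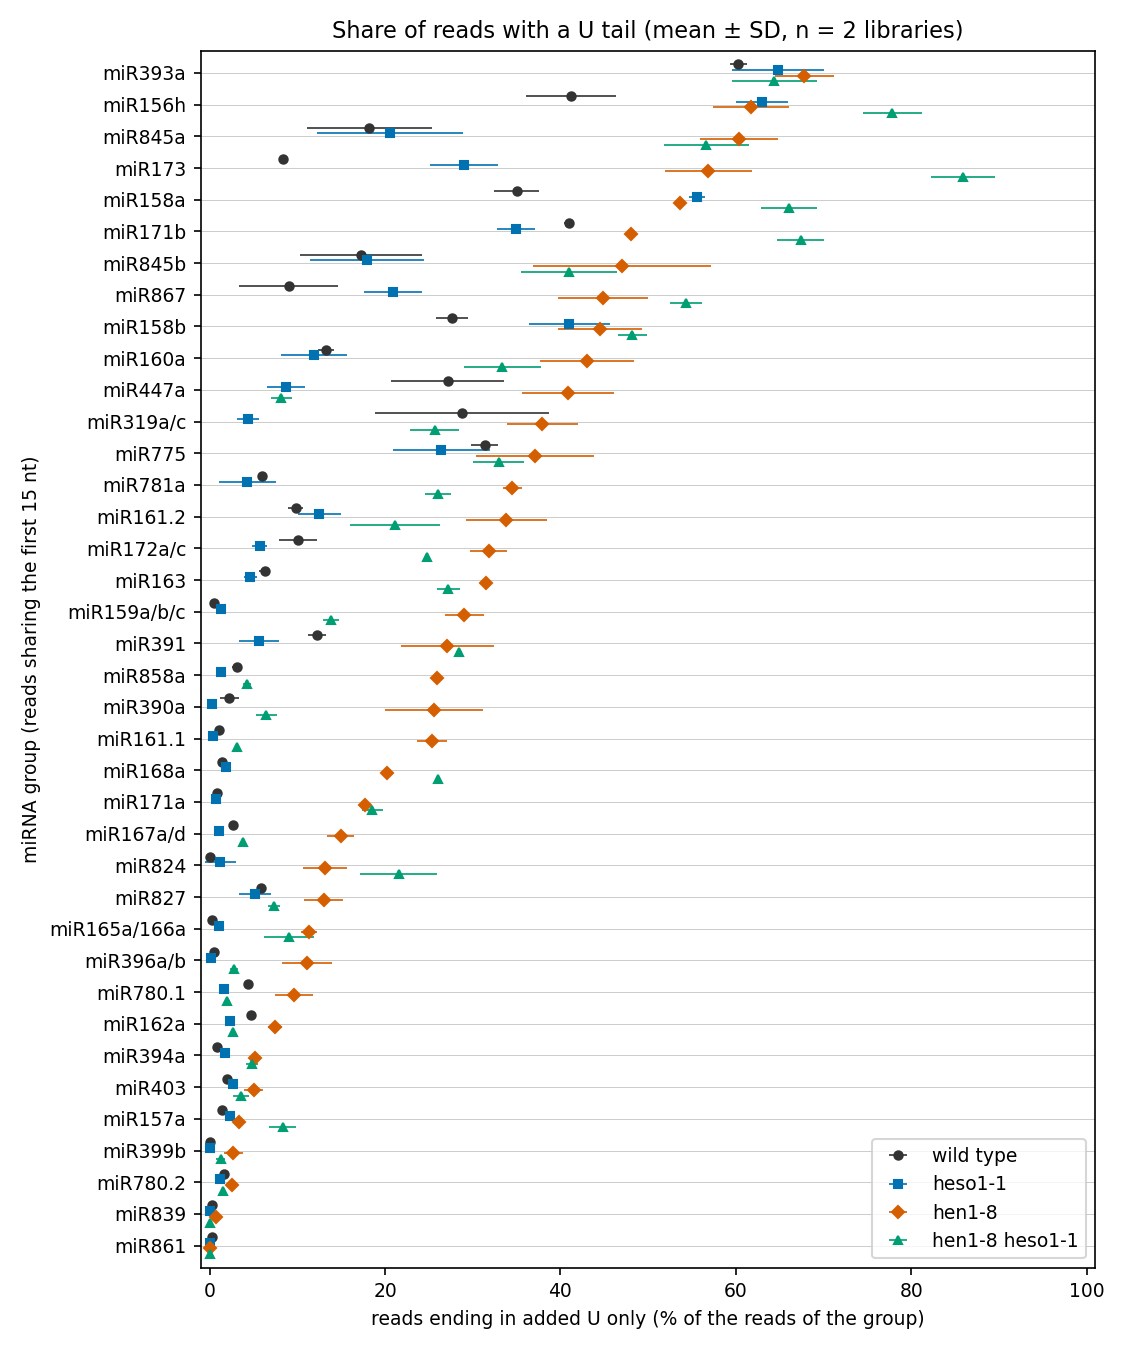
U-tailed share of reads (%) for each miRNA group in the 4 genotypes, as mean ± SD of 2 libraries. miR159a/b/c lies at 0.521% in wild type and 29.1% in hen1-8, and miR173 at 56.9% in hen1-8 and 85.9% in the double mutant.

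The truncated untailed share also rose in hen1-8 against wild type, in 16 of 38 groups, with 0 falls by edgeR. miR165a/miR166a went from 1.83% ± 0.385 to 53.9% ± 1.62 (SD, n = 2; log2 odds ratio 5.99 ± 0.27, adjusted p = 9.85e-08). miR839 went from 3.37% ± 1.14 to 57.6% ± 3.14 (5.24 ± 0.37, adjusted p = 1.21e-06) and miR394a from 2.79% ± 0.410 to 22.1% ± 1.32 (3.32 ± 0.25, adjusted p = 1.4e-06). miR167a/d (3.14), miR396a/b (2.90), miR319a/c (2.73), miR168a (2.64), miR159a/b/c (2.57), miR160a (2.14), miR403 (1.86), miR163 (1.27) and miR162a (0.75) rose as well, with adjusted p from 1.62e-07 to 0.00891. miR160a did not pass without wild-type replicate 1 (adjusted p = 0.104). Truncated untailed forms of miR390a and miR824 had 0 reads in all 8 libraries, and their absence is not read as a result, since such reads may be missing from the files used here. The other shares of miR390a and miR824 rest on the forms present. When truncated reads with a tail were counted as well, 30 groups rose. When 2 nt or more had to be missing, 8 rose and 1 fell, and miR160a, miR162a, miR167a/d, miR396a/b and miR403 did not pass (adjusted p = 0.123 to 0.666).

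The share of reads whose tail held a base other than U rose in 28 of 38 groups in hen1-8 against wild type, with 0 falls by edgeR. miR824 went from 4.98% ± 0.725 to 81.5% ± 4.13 (SD, n = 2; log2 odds ratio 6.42 ± 0.43, adjusted p = 2.19e-05). miR396a/b went from 0.793% ± 0.521 to 15.5% ± 0.783 (4.62 ± 0.50, adjusted p = 0.000193) and miR159a/b/c from 0.914% ± 0.251 to 17.2% ± 1.33 (4.51 ± 0.22, adjusted p = 3.2e-06). miR165a/miR166a (3.83), miR163 (3.64), miR171a (3.27), miR168a (3.19), miR390a (2.84), miR161.1 (2.79), miR172a/c (2.74), miR167a/d (2.66), miR319a/c (2.44), miR394a (2.29), miR173 (2.02), miR157a (1.29), miR403 (0.90) and miR156h (0.52) also rose. Leaving out 1 library ended the call of miR173 (adjusted p = 0.0537 without wild-type replicate 1 and 0.0525 without hen1-8 replicate 1). It also ended that of miR403 (0.0587 to 0.231 without wild-type replicate 2 or any 1 hen1-8 or double mutant library) and of miR156h (0.0848 to 0.184 without any 1 wild-type, hen1-8 or double mutant library). The call of miR156h was also lost with the replicate number as a block (adjusted p = 0.0550) and with a threshold of 20 reads (0.0708), and that of miR390a with tails of 2 nt or more (0.0684).

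Counted over all of their 3′ forms, 22 of 77 miRNA groups changed in abundance in hen1-8 against wild type, 14 up and 8 down (33 at an unadjusted p under 0.05). miR159a/b/c fell from 14697 ± 2869 to 4220 ± 916 RPM (read counts scaled to library size; SD, n = 2; log2 fold change -1.80 ± 0.23 SE, adjusted p = 0.00172). miR161.1 went from 339.6 ± 13.3 to 97.2 ± 27.9 (-1.81 ± 0.28, adjusted p = 0.0028) and miR319a/c from 9901 ± 123 to 6007 ± 412 (-0.72 ± 0.18, adjusted p = 0.0224). The largest falls were in miR829 (-4.51 ± 1.28, adjusted p = 0.0358), miR780.1 (212 ± 78.5 to 28.2 ± 8.20 RPM, -2.91 ± 0.49, adjusted p = 0.00409) and miR846 (-2.70 ± 0.69, adjusted p = 0.0226). The largest rises were in miR402, on chromosome 1 at 29016586 to 29016607 in AT1G77235 (6.47 ± 1.66 to 132 ± 45.5 RPM, 4.35 ± 0.42, adjusted p = 0.000633), miR393a, a regulator of auxin receptors (30.8 ± 4.46 to 485 ± 61.3, 3.97 ± 0.22, adjusted p = 2.52e-05), and miR776 (3.46 ± 0.46, adjusted p = 0.00177). miR160a, which targets auxin response factors (3.03 ± 0.35), miR173 (2.22 ± 0.27), miR167a/d (1.24 ± 0.22) and miR162a (726 ± 44.4 to 1698 ± 78.2, 1.23 ± 0.17) also rose. Without their tailed and truncated forms the picture was mostly of falls: the full-length untailed form rose in 4 and fell in 31 of 74 groups, and miR167a/d then fell (-2.04) while miR160a and miR173 did not pass (log2 fold changes 0.02 and 0.04), nor did miR402 (2.13, adjusted p = 0.15). Scaled to organelle, tRNA, rRNA, snRNA and snoRNA reads, a scale chosen after the data were seen, 47 groups rose and 1 fell and the median moved from 0.05 to 1.52. On that scale miR159a/b/c stood at -0.34 and miR161.1 at -0.37 (not passing) and miR319a/c at 0.77 (adjusted p = 0.0605), and miR829 (-3.09, adjusted p = 0.0547) and miR846 (-1.30, adjusted p = 0.0782) did not pass. With DESeq2 16 rose and 14 fell, and with the replicate number as a block 21 rose and 17 fell. Leaving out 1 library ended the calls of miR319a/c (adjusted p = 0.0681 to 0.122 without any 1 wild-type or hen1-8 library and 0.0509 without double mutant replicate 2), miR829 (0.0501 to 0.196 without wild-type replicate 1 or any 1 hen1-8 or double mutant library) and miR846 (0.0819 without wild-type replicate 1 and 0.118 without hen1-8 replicate 2).

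Of 19 developmental regulators tested for abundance, 3 rose and 2 fell (the same counts adjusted over the list alone; fry adjusted p = 0.0803, with a median of -0.02 and a mean of 0.18). Nutrient regulators, which respond to phosphate, copper and sulfate, had 0 of 9 passing by edgeR (fry adjusted p = 0.0803). Of the 3 small RNA pathway regulators, miR162a rose (fry adjusted p = 0.331, with a median of -0.30 and a mean of 0.12). Of the 2 ta-siRNA triggers, miR173 rose (fry adjusted p = 0.0186 and, with an estimated correlation, adjusted p = 0.969). Narrowly conserved miRNAs had 9 rises and 6 falls among 45 (fry adjusted p = 0.476, with a median of -0.02 and a mean of 0.02). Of 16 miRNAs longer than 21 nt, 7 rose and 1 fell (7 and 2 adjusted over the list alone). fry called this list (adjusted p = 0.00375), and with an estimated correlation adjusted p = 0.87. Of 13 miRNAs with a 5′ base other than U, 2 rose and 1 fell (the same adjusted over the list alone), and fry put the list up (adjusted p = 0.617) although its median was -0.19 and its mean -0.13. fry's mixed test passed the developmental, small RNA pathway, narrowly conserved, longer and other 5′ base lists (adjusted p of 0.00906 or less), and not the nutrient (0.332) or trigger (0.0703) list. Adjusted over the list alone, the counts were also the same for the nutrient, small RNA pathway, trigger and narrowly conserved lists.

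Single-match 24-nt reads were counted in 28763 windows of 500 bp, and 18018 windows fell and 120 rose in hen1-8 against wild type by edgeR (median log2 ratio -1.19). Such reads made up 41.2 and 38.3% of the wild-type libraries and 16.3 and 16.8% of the hen1-8 libraries. Falls covered 69.6% of 13529 windows between genes, 69.2% of 4761 windows over protein-coding genes and 48.1% of 9037 windows over pseudogenes, a class that holds many transposon remnants in this annotation. The largest falls were to 0 reads. The window at chromosome 1, 27597501 to 27598000 (TAIR10.1; between genes, 33 bp from AT1G73400) held 715 wild-type reads and 0 hen1-8 reads, at least 442-fold lower against a floor of 3 counts over the group (adjusted p = 3.16e-12). Chromosome 3, 22076001 to 22076500, over an exon of the noncoding RNA gene AT3G59765, was at least 286-fold lower (463 to 0 reads), and chromosome 3, 16462501 to 16463000, 1094 bp from AT3G45000, at least 125-fold lower (202 to 0). The largest rises started from 0 wild-type reads. They were at chromosome 1, 26395001 to 26395500 in the coding sequence of AT1G70080 (200 hen1-8 reads, at least 35.9-fold, adjusted p = 4.02e-08), chromosome 3, 3063501 to 3064000 over AT3G09960 and AT3G09970 (48 reads, at least 8.62-fold), and chromosome 4, 57001 to 57500 in the coding sequence of HAM3, AT4G00150, a GRAS gene (47 reads, at least 8.44-fold). The counts depend on the scale of the libraries: with TMM factors 4057 windows fell and 2039 rose (median 0.01), with DESeq2 2739 fell and 1002 rose, and scaled to organelle and structural reads, as above, 2212 fell and 2880 rose (median 0.41). Windows of 20- to 22-nt reads gave 2480 rises and 1392 falls of 13108.

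In the double mutant against hen1-8, U tails were shorter in 29 of 39 miRNA groups and longer in 0 (limma with Benjamini-Hochberg adjustment, 31 at an unadjusted p under 0.05). miR160a went from a mean of 2.89 ± 0.0874 nt to 1.14 ± 0.0120 nt (SD, n = 2; difference -1.75 ± 0.06 nt SE, adjusted p = 0.000514). miR163 went from 4.39 ± 0.339 to 2.78 ± 0.0969 nt (-1.61 ± 0.18, adjusted p = 0.00416) and miR780.1 from 2.84 ± 0.280 to 1.58 ± 0.219 nt (-1.26 ± 0.19, adjusted p = 0.00705). miR157a (-1.18), miR165a/miR166a (-1.03), miR161.1 (-0.98), miR159a/b/c (-0.78), miR394a (-0.74), miR162a (-0.67), miR171a (-0.61), miR158a (-0.45), miR158b (-0.43), miR173 (-0.43), miR168a (-0.31), miR403 (-0.27), miR393a (-0.23) and miR156h (-0.17) were shorter as well. miR390a had tails of 1.07 nt in both genotypes (adjusted p = 0.958), and miR319a/c (-0.05), miR396a/b (-0.10), miR172a/c (0.13) and miR167a/d (-0.25, adjusted p = 0.0618) did not pass. Medians over the 39 groups were 1.52 and 1.58 nt in the wild-type libraries, 1.40 and 1.35 nt in heso1-1, 1.77 and 1.81 nt in hen1-8, and 1.35 and 1.29 nt in the double mutant. U tails of 4 nt or more, a split added after the data were seen, fell in share in 30 of 38 groups and rose in 0 by edgeR. With either double mutant library left out, 0 groups passed the length test (adjusted p of the called groups named here 0.0571 to 0.242), but the median difference stayed at -0.41 nt with either left out, against -0.43 with all 4 libraries. With either hen1-8 library left out 33 groups passed. In each of these fits 1 genotype has a single library and the spread comes from the other alone, so the lost calls do not show a loss of the shortening. miR156h also did not pass without hen1-8 replicate 1 (adjusted p = 0.0745) or with the replicate number as a block (0.0526). On full-length prefixes alone, 10 of 27 groups were shorter, and miR158a (0.05 nt), miR158b (0.02 nt) and miR168a (0.26 nt) had the opposite sign, while miR156h, miR161.1, miR162a and miR173 did not pass (adjusted p = 0.085 to 0.261).

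**Figure D4:**
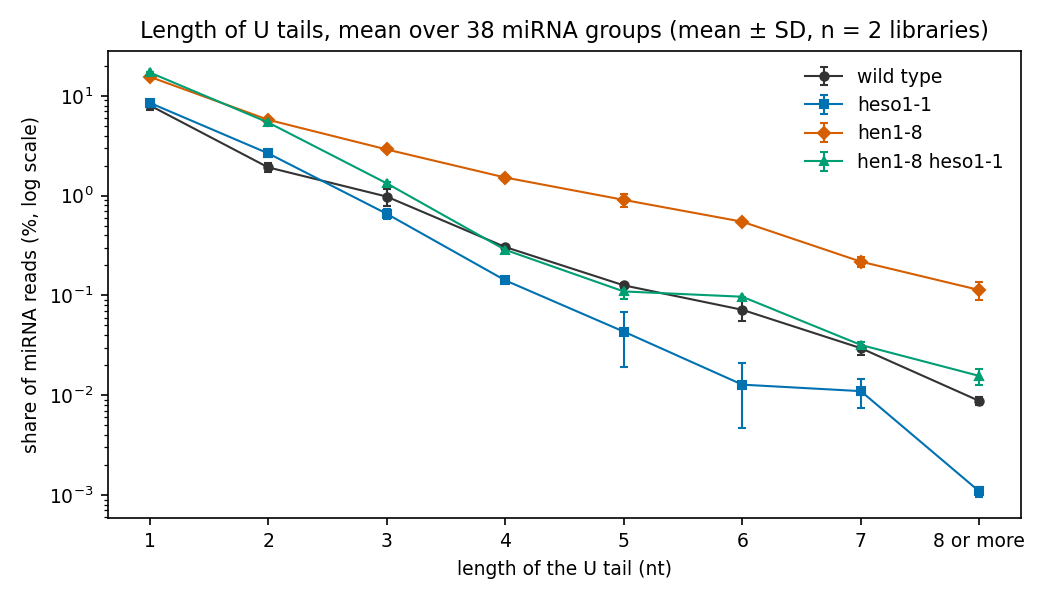
Share of miRNA reads (%, log scale) by length of the U tail (nt) in the 4 genotypes, averaged over 38 miRNA groups and shown as mean ± SD of 2 libraries. At 4 nt the share is 1.52% in hen1-8 and 0.287% in the double mutant, and at 2 nt it is 5.76 and 5.42%.

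The share of U-tailed reads fell in 14 groups and rose in 5 of 38 in the double mutant against hen1-8. miR161.1 fell from 25.4% ± 1.71 to 3.07% ± 0.228 (SD, n = 2; log2 odds ratio -3.42 ± 0.23, adjusted p = 2.54e-09). miR858a, which targets MYB genes of flavonoid synthesis and maps to chromosome 1 at 26773695 to 26773715, fell from 25.9% ± 0.492 to 4.27% ± 0.437 (-2.97 ± 0.21, adjusted p = 2.59e-09), and miR839 from 0.708% to 0.0422% (-3.67 ± 0.84, adjusted p = 0.00152). miR390a fell from 25.6% ± 5.59 to 6.46% ± 1.21 (-2.32 ± 0.29, adjusted p = 3.12e-06) and miR159a/b/c from 29.1% ± 2.18 to 13.8% ± 0.896 (-1.35 ± 0.24, adjusted p = 0.000133). miR167a/d (-2.15), miR396a/b (-2.11), miR162a (-1.57), miR319a/c (-0.83) and miR160a (-0.61) also fell. The rises were in miR173, from 56.9% ± 4.97 to 85.9% ± 3.63 (2.21 ± 0.29, adjusted p = 3.84e-06). miR157a, went from 3.36% ± 0.0420 to 8.33% ± 1.57 (1.37 ± 0.22, adjusted p = 3.58e-05), miR171b (1.16 ± 0.26), miR156h (1.11 ± 0.27) and miR158a, from 53.6% ± 0.424 to 66.1% ± 3.17 (0.76 ± 0.25, adjusted p = 0.019). Each of these 5 had the opposite sign when only tails of 2 nt or more were counted (-0.20, -0.63, -0.09, -0.58 and -1.30), and on that measure 20 groups fell and 0 rose. Falls that did not pass on it were those of miR319a/c (adjusted p = 0.061), miR390a (0.0777) and miR839 (0.0647). limma did not pass miR160a (0.175) and miR319a/c (0.132), and neither passed under a further setting each (miR160a 0.0725 with genome-matching reads never tailed, miR319a/c 0.0566 with 200 reads). miR157a did not pass when tails with a majority of U were counted (0.365). The calls of miR160a (adjusted p = 0.0889 to 0.359 without wild-type replicate 1 or 2, hen1-8 replicate 2 or double mutant replicate 1), miR158a (0.112 to 0.137 without hen1-8 replicate 1 or 2 or double mutant replicate 1) and miR319a/c (0.155 without hen1-8 replicate 1 and 0.142 without double mutant replicate 2) were lost when 1 library was left out. The log2 odds ratios there kept their sign (-0.37 to -0.61, 0.61 to 0.77, and -0.65 and -0.68). U-tailed shares on full-length prefixes, also split after seeing the data, fell in 27 groups and rose in 4 (9 and 6 if truncated).

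Among the lists, developmental regulators had 3 rises and 6 falls of 14 in U-tailed share (the same adjusted over the list alone; fry adjusted p = 0.00559), and narrowly conserved miRNAs 1 rise and 7 falls of 18 (the same adjusted over the list alone; 0.00476). Small RNA pathway regulators had 1 fall of 3, miR162a (1 rise and 1 fall adjusted over the list alone; 0.0211), and the 2 nutrient regulators did not pass over all groups but both fell adjusted over the list alone (0.0211). Longer miRNAs had 1 rise and 2 falls (0.0211) and miRNAs with another 5′ base 1 fall (0.00701), both with the same counts adjusted over the list alone. The 2 triggers moved apart, miR173 up and miR390a down (adjusted p = 0.822; the same adjusted over the list alone), with a median of -0.05 where fry gave an upward direction. With an estimated correlation, adjusted p = 0.957 for every list. The mixed test passed the developmental, narrowly conserved, longer and other 5′ base lists (adjusted p of 0.00167 or less) and not the small RNA pathway (0.0504), trigger (0.116) and nutrient (0.31) lists.

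The share of reads whose tail held a base other than U fell in 30 of 38 groups in the double mutant against hen1-8, with 0 rises by edgeR. miR160a fell from 34.1% ± 4.21 to 1.62% ± 0.105 (SD, n = 2; log2 odds ratio -4.96 ± 0.78, adjusted p = 0.00125). miR858a went from 15.6% ± 3.11 to 1.19% ± 0.488 (-3.95 ± 0.51, adjusted p = 0.000509). miR161.2 went from 9.12% ± 0.702 to 0.798% ± 0.469 (-3.77 ± 0.61, adjusted p = 0.00125) and miR165a/miR166a from 8.68% ± 0.591 to 0.720% ± 0.0387 (-3.71 ± 0.16, adjusted p = 1.71e-06). miR159a/b/c (-3.17), miR394a (-3.07), miR163 (-2.80), miR173 (-2.64), miR396a/b (-2.37), miR162a (-2.23), miR171a (-2.21), miR161.1 (-1.80), miR403 (-1.76), miR393a (-1.69), miR167a/d (-1.65), miR158a (-1.60), miR172a/c (-1.35), miR168a (-1.32), miR319a/c (-1.05), miR156h (-0.69) and miR158b (-0.68) fell too. miR157a (-0.48, adjusted p = 0.126) and miR390a (-0.84, adjusted p = 0.056) did not pass. Leaving out 1 library ended the calls of miR156h (adjusted p = 0.0617 to 0.0744 without hen1-8 replicate 1 or 2 or double mutant replicate 2), miR158b and miR161.1 (0.0557 to 0.116 without any 1 library of either genotype), miR168a (0.0728 without hen1-8 replicate 1) and miR393a (0.0533 without double mutant replicate 2). The log2 odds ratios there were -0.63 to -0.69 for miR156h, -0.64 to -0.71 for miR158b, -1.63 to -1.97 for miR161.1, -1.06 for miR168a and -1.47 for miR393a.

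The truncated untailed share rose in 20 of 38 groups in the double mutant against hen1-8 and fell in 0 by edgeR. miR159a/b/c went from 14.9% ± 0.129 to 65.6% ± 0.187 (SD, n = 2; log2 odds ratio 3.44 ± 0.13, adjusted p = 2.47e-08). miR447a went from 36.1% ± 5.20 to 85.7% ± 0.506 (3.38 ± 0.25, adjusted p = 3.72e-06). miR160a went from 14.8% ± 1.04 to 53.7% ± 3.06 (2.74 ± 0.33, adjusted p = 7.16e-05). miR163 went from 14.6% ± 4.76 to 51.1% ± 0.321 (2.65 ± 0.24, adjusted p = 1.29e-05) and miR167a/d from 52.9% ± 1.77 to 82.7% ± 1.33 (2.10 ± 0.21, adjusted p = 2.18e-05). miR399b (3.10), miR157a (2.74), miR172a/c (1.66), miR396a/b (1.47), miR394a (1.36), miR165a/miR166a (1.00), miR161.1 (0.99), miR168a (0.86) and miR319a/c (0.81) rose as well. miR403 (0.03, adjusted p = 0.895) and miR162a (-0.14, adjusted p = 0.431) did not pass. Counted with or without a tail, truncation of miR161.1 fell (-1.88), and miR160a (-0.30) and miR163 (-0.85) also had a negative sign. With or without a tail, miR165a/miR166a, miR396a/b and miR399b did not pass (adjusted p = 0.0774 to 0.0924), and miR168a did not pass with limma (0.0573). With 2 nt or more missing, 12 groups rose, miR161.1 stood at -0.25, and miR160a, miR167a/d, miR396a/b and miR399b did not pass (0.073 to 0.376). The calls of miR168a (adjusted p = 0.0731 to 0.125 without hen1-8 replicate 1 or 2 or double mutant replicate 1), miR399b (0.0901 without hen1-8 replicate 1), miR161.1 (0.0648 without hen1-8 replicate 2) and miR165a/miR166a (0.073 without hen1-8 replicate 2) were lost when 1 library was left out.

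**Figure D5:**
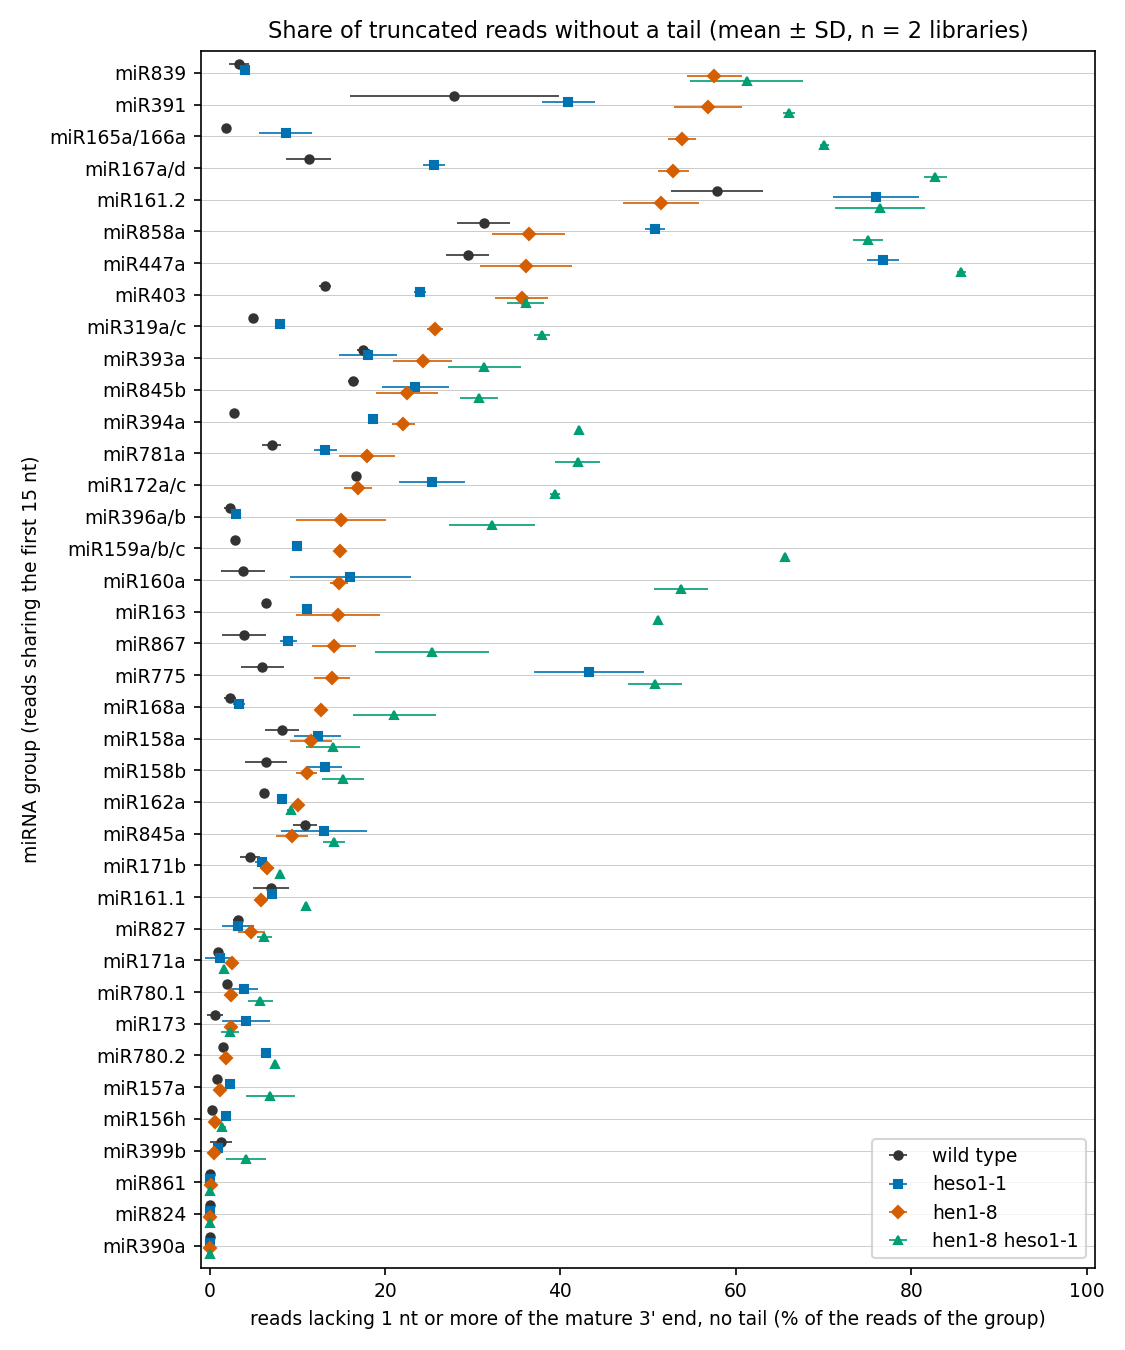
Share of truncated untailed reads (%) for each miRNA group in the 4 genotypes, as mean ± SD of 2 libraries. miR159a/b/c lies at 2.88% in wild type, 9.94% in heso1-1, 14.9% in hen1-8 and 65.6% in the double mutant.

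In abundance over all 3′ forms, 9 miRNA groups rose and 2 fell of 77 in the double mutant against hen1-8 (31 at an unadjusted p under 0.05). miR159a/b/c rose from 4220 ± 916 to 17166 ± 1295 RPM (SD, n = 2; log2 fold change 2.02 ± 0.24, adjusted p = 0.00212). miR161.2 went from 1004 ± 34.1 to 4112 ± 133 (2.03 ± 0.21, adjusted p = 0.0018) and miR161.1 from 97.2 ± 27.9 to 308 ± 82.9 (1.66 ± 0.28, adjusted p = 0.0101). The 3 largest rises were in miR778 (3.57 ± 0.65, adjusted p = 0.014), miR862 (2.63 ± 0.57, adjusted p = 0.0277) and miR780.2 (2.07 ± 0.27, adjusted p = 0.00304). miR167a/d rose (0.87 ± 0.22, adjusted p = 0.0407), and miR776 (-2.06 ± 0.43, adjusted p = 0.0251) and miR162a (1698 ± 78.2 to 1017 ± 48.7, -0.74 ± 0.17, adjusted p = 0.0303) fell. miR165a/miR166a (1.71 ± 0.51, adjusted p = 0.0556) and miR319a/c (0.59, adjusted p = 0.0565) did not pass. The median over groups was 0.74 on this scale and 0.05 with TMM factors, which gave 4 rises and 7 falls; DESeq2 gave 7 rises and 10 falls and the replicate block 27 rises and 7 falls. Full-length untailed forms gave 3 rises and 1 fall, with miR167a/d at -0.09 and miR159a/b/c (0.94, adjusted p = 0.0965), miR162a (0.132) and miR862 (0.132) not passing. With TMM factors miR161.1 (0.0577), miR862 (0.0533) and miR167a/d (0.675) did not pass, and DESeq2 did not pass miR167a/d (0.356) and gave no adjusted p for miR778 and miR862. The count was 7 without hen1-8 replicate 1, 2 without hen1-8 replicate 2, 3 without double mutant replicate 1 and 5 without double mutant replicate 2. Among these calls, miR167a/d did not pass without any 1 of the 8 libraries (adjusted p = 0.0526 to 0.179). miR162a (0.0502 to 0.174) did not pass without wild-type replicate 1 or any 1 hen1-8 or double mutant library, and miR776 (0.0682 to 0.134) without any 1 library of those genotypes. Without hen1-8 replicate 2, miR778 (0.107), miR862 (0.119), miR161.1 (0.0779) and miR780.2 (0.0536) did not pass. Without double mutant replicate 1, miR778 (0.0597), miR862 (0.121) and miR161.1 (0.0597) did not pass. Further losses were miR778 without hen1-8 replicate 1 (0.071) and miR862 without double mutant replicate 2 (0.0603).

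By list, fry called upward movement for developmental regulators (2 rises of 19, 1 adjusted over the list alone; adjusted p = 0.0143), nutrient regulators (1 of 9, miR778, also adjusted over the list alone; 0.0386), narrowly conserved miRNAs (6 rises and 1 fall of 45, 9 and 1 adjusted over the list alone; 0.0444) and longer miRNAs (1 of 16, 0 adjusted over the list alone; 0.0281). With an estimated correlation, adjusted p = 0.852 for each. Small RNA pathway regulators had 1 fall of 3, also adjusted over the list alone (adjusted p = 0.537, with a median of 0.19 and a mean of -0.08). The triggers had 0 of 2 passing by edgeR (1 rise adjusted over the list alone; adjusted p = 0.116) and miRNAs with another 5′ base 0 of 13 (0 adjusted over the list alone; 0.544). The mixed test passed all lists (adjusted p of 0.032 or less) but these last 2 (0.208 and 0.166).

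Of the 24-nt windows, 822 rose and 139 fell in the double mutant against hen1-8 by edgeR (4300 at an unadjusted p under 0.05, median log2 ratio 0.13). Single-match 24-nt reads made up 16.3 and 16.8% of the hen1-8 libraries and 19.3 and 20.1% of the double mutant libraries. Windows between genes gave 521 rises and 84 falls, protein-coding genes 153 and 34, and pseudogenes 100 and 13. The largest rises were at chromosome 2, 10241001 to 10241500, between genes and 375 bp from AT2G24090 (1 read in hen1-8 and 133 in the double mutant, a ratio of 165 with a 95% counting interval of 29 to 6551) and chromosome 5, 521501 to 522000, 1257 bp from AT5G02420 (1 and 120 reads, ratio 149, 26.2 to 5915). The third was at chromosome 1, 12561501 to 12562000, 186 bp from the noncoding RNA gene AT1G34392 (0 and 16 reads, at least 6.60-fold). It did not pass without hen1-8 replicate 2 (adjusted p = 0.114) or double mutant replicate 1 (0.0727). The largest falls were at chromosome 4, 15548501 to 15549000 in the coding sequence of ASY2, AT4G32200, an axis protein of meiotic chromosomes (141 to 0 reads, at least 38-fold). The others were at chromosome 2, 4558501 to 4559000 over pseudogene AT2G11420 (212 to 1 read, ratio 171, 30.4 to 6796) and chromosome 5, 19198501 to 19199000 in the coding sequence of AT5G47300 (43 to 0 reads, at least 11.6-fold). DESeq2 gave no adjusted p for the windows at 10241001 on chromosome 2, 15548501 on chromosome 4 and 19198501 on chromosome 5. TMM factors gave 505 rises and 169 falls (median 0.00), and the replicate block 2072 and 437. The count was 385 without hen1-8 replicate 1, 561 without hen1-8 replicate 2 and 355 without double mutant replicate 2. Windows of 20- to 22-nt reads gave 2736 rises and 103 falls.

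In heso1-1 against wild type, where HEN1 is intact, the truncated untailed share rose in 17 of 38 miRNA groups and fell in 0 by edgeR. miR775 went from 6.03% ± 2.41 to 43.3% ± 6.24 (SD, n = 2; log2 odds ratio 3.65 ± 0.39, adjusted p = 3.77e-05). miR394a, which targets the F-box gene LCR, went from 2.79% ± 0.410 to 18.6% ± 0.317 (3.02 ± 0.25, adjusted p = 7.34e-06). miR447a went from 29.5% ± 2.45 to 76.8% ± 1.80 (3.01 ± 0.31, adjusted p = 3.77e-05). miR165a/miR166a went from 1.83% ± 0.385 to 8.68% ± 3.01 (2.32 ± 0.25, adjusted p = 4.11e-05) and miR159a/b/c from 2.88% ± 0.108 to 9.94% ± 0.259 (1.90 ± 0.13, adjusted p = 4.48e-06). miR403 went from 13.2% ± 0.711 to 24% ± 0.677 (1.05 ± 0.16, adjusted p = 0.0005) and miR167a/d from 11.3% ± 2.59 to 25.6% ± 1.24 (1.43 ± 0.22, adjusted p = 0.000542). miR160a (2.33), miR157a (1.46), miR158b (1.20), miR163 (0.85), miR172a/c (0.77), miR319a/c (0.73) and miR162a (0.45) rose as well. The count was 11 without heso1-1 replicate 2 and 8 when 2 nt or more had to be missing. Leaving out 1 library ended the calls of miR160a (adjusted p = 0.0888 without wild-type replicate 1 and 0.0979 without heso1-1 replicate 2) and miR158b (0.133 and 0.126 without the same libraries). It also ended those of miR157a (0.0782 to 0.159) and miR163 (0.0666 to 0.104) without any 1 wild-type or heso1-1 library, miR162a (0.0712 to 0.201) without any 1 of these or of the double mutant, and miR172a/c (0.0577 to 0.159) without any 1 library except heso1-1 replicate 1. Counted with or without a tail, miR162a (-0.22) and miR163 (-0.01) had the opposite sign, as did miR158b with 2 nt or more missing (-0.40). With or without a tail miR160a (0.718) did not pass, and with 2 nt or more missing miR160a, miR162a, miR167a/d, miR172a/c, miR447a and miR775 did not (0.101 to 0.855). Other thresholds and limma ended the calls of miR162a (0.057 with 20 reads and 0.0662 with limma), miR172a/c (0.057 with 20 reads) and miR157a (0.052 with 200 reads).

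The U-tailed share fell in 9 groups and rose in 9 of 38 in heso1-1 against wild type. miR319a/c fell from 28.8% ± 9.96 to 4.34% ± 1.26 (SD, n = 2; log2 odds ratio -3.15 ± 0.33, adjusted p = 1.49e-06) and miR390a from 2.25% ± 1.10 to 0.259% ± 0.0569 (-3.16 ± 0.51, adjusted p = 0.000206). miR447a fell from 27.1% ± 6.44 to 8.70% ± 2.13 (-2.07 ± 0.45, adjusted p = 0.00132), and miR396a/b (-1.45), miR858a (-1.38), miR167a/d (-1.35), miR161.1 (-1.32) and miR162a (-1.12) fell as well. The rises included miR173, from 8.41% ± 0.485 to 29% ± 3.84 (2.10 ± 0.53, adjusted p = 0.00373). miR158a, went from 35.0% ± 2.58 to 55.6% ± 0.955 (1.22 ± 0.25, adjusted p = 0.00117), and miR156h, from 41.2% ± 5.10 to 63.0% ± 2.93 (1.30 ± 0.30, adjusted p = 0.00179). miR165a/miR166a (1.75), miR867 (1.35), miR159a/b/c (0.521% ± 0.0754 to 1.29% ± 0.0115, 1.32), miR394a (1.02), miR158b (0.87) and miR157a (0.73) also rose. U tails of 4 nt or more fell in 9 groups and rose in 0 by edgeR, among them miR158a (-3.53, adjusted p = 4.12e-05), miR158b, miR161.1, miR162a, miR163 and miR319a/c. With tails of 2 nt or more, 3 groups rose and 4 fell, and miR158a (-0.70), miR158b (-0.32), miR167a/d (0.13) and miR319a/c (0.42) had the opposite sign. On that measure miR156h, miR157a, miR161.1, miR165a/miR166a, miR173, miR390a, miR394a, miR396a/b and miR867 did not pass (adjusted p = 0.111 to 0.922). When tails with a majority of U were counted, miR157a (0.759), miR394a (0.119) and miR867 (0.133) did not pass, and neither did miR157a with a prefix of 17 nt or more (0.0601). Without wild-type replicate 1, miR156h (adjusted p = 0.0548), miR173 (0.0548), miR165a/miR166a (0.0635), miR161.1 (0.0635), miR394a (0.0635) and miR157a (0.145) did not pass. Without wild-type replicate 2, the same held for miR157a (0.0936), miR158b (0.0766), miR394a (0.167), miR396a/b (0.0936) and miR867 (0.178), and without heso1-1 replicate 2 for miR157a (0.212), miR158b (0.0605), miR161.1 (0.0626) and miR396a/b (0.0605). Calls also ended without heso1-1 replicate 1 (miR394a, miR867) or hen1-8 replicate 1 (miR157a) or 2 (miR157a, miR394a).

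No list passed fry's one-way test of the U-tailed share in heso1-1 (adjusted p of 0.281 or more, and 0.987 with an estimated correlation). The lowest unadjusted p was 0.0416, for miRNAs with another 5′ base (median -0.90, mean -1.14). Developmental regulators had 5 rises and 4 falls of 14 (5 and 5 adjusted over the list alone), and narrowly conserved miRNAs 3 and 4 of 18 (the same adjusted over the list alone). When either direction counted (fry's mixed test), both lists passed (adjusted p = 0.00041 and 5.86e-05), as did longer miRNAs (0.00232), miRNAs with another 5′ base (0.00232) and small RNA pathway regulators (0.038). The counts of rises and falls were 0 and 1 for small RNA pathway regulators (median 0.42, mean -0.09, direction down), 1 and 1 for triggers, 0 and 0 for nutrient regulators by edgeR and 1 and 2 for longer miRNAs, with the same counts adjusted over the list alone. They were 1 and 1 for miRNAs with another 5′ base (1 and 2 adjusted over the list alone). In abundance, miR161.2 was the single miRNA group of 77 that changed in heso1-1, from 492 ± 87.5 to 1509 ± 270 RPM (log2 fold change 1.62 ± 0.20, adjusted p = 0.00736), with 9 groups at an unadjusted p under 0.05. It shares its hairpin with miR161.1 (chromosome 1, 17825722 to 17825742 and 17825731 to 17825751, AT1G48267). The count was 0 without wild-type replicate 1 (adjusted p of miR161.2 0.0904), without heso1-1 replicate 2 (0.0621), with TMM factors and for full-length untailed reads. It was 2 with DESeq2 and 5 with the replicate block. The median moved from 0.25 to -0.48 with TMM factors. Of the lists, the narrowly conserved miRNAs held this 1 rise, the others 0 by edgeR, all with the same counts adjusted over the list alone (fry adjusted p of 0.146 or more; mixed test 0.0274 for narrowly conserved miRNAs and 0.404 or more for the others).

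Of the 24-nt windows, 111 rose and 146 fell in heso1-1 against wild type (1364 at an unadjusted p under 0.05, 169 by DESeq2 and 443 with the replicate block). Between genes, 62 windows rose and 77 fell, and over protein-coding genes 39 and 48. The largest rises were from 0 wild-type reads, at chromosome 1, 26395001 to 26395500 in AT1G70080 (462 reads in heso1-1, at least 136-fold, adjusted p = 3.65e-09), chromosome 3, 15777001 to 15777500 in the coding sequence of AT3G43970 (395 reads, at least 116-fold) and chromosome 5, 521501 to 522000 (345 reads, at least 102-fold). The largest falls were to 0 reads, at chromosome 3, 15796001 to 15796500 over AT3G44005 and AT3G44006 (211 wild-type reads, at least 79.5-fold), chromosome 5, 17729001 to 17729500 (144 reads, at least 54.3-fold) and chromosome 3, 1165501 to 1166000 in the coding sequence of AT3G04390 (138 reads, at least 52.0-fold). The count was 165 without heso1-1 replicate 2, and windows of 20- to 22-nt reads gave 42 rises and 32 falls.

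The effect of HESO1 loss was compared between the hen1-8 and wild-type backgrounds by an interaction term. For the U-tailed share the effect was more negative in hen1-8 for miR159a/b/c (log2 ratio of odds ratios -2.67 ± 0.34, adjusted p = 2.74e-05), miR165a/miR166a (-2.14 ± 0.52, adjusted p = 0.00715), miR161.1 (-2.10 ± 0.44, adjusted p = 0.0024), miR858a (-1.59 ± 0.44, adjusted p = 0.0117) and miR161.2 (-1.33 ± 0.36, adjusted p = 0.0117). It was more positive in hen1-8 for miR319a/c (2.32 ± 0.45, adjusted p = 0.00177) and miR171b (1.53 ± 0.38, adjusted p = 0.00755). These 7 of 38 groups passed (10 at an unadjusted p under 0.05, and 12 passed with the replicate block, 3 up and 9 down). The U-tailed share of miR159a/b/c was higher with HESO1 loss in one background (0.521 to 1.29%) and lower in the other (29.1 to 13.8%), where its abundance over all forms rose (4220 to 17166 RPM). The call of miR165a/miR166a was lost without wild-type replicate 1 (adjusted p = 0.118) and that of miR171b without double mutant replicate 1 (0.0535), and limma did not pass miR165a/miR166a (0.0649). With tails of 2 nt or more, miR171b (-2.20) and miR319a/c (-0.96) had the opposite sign. By list, developmental regulators had 2 positive and 2 negative terms and narrowly conserved miRNAs 0 and 3, the other lists 0 by edgeR, with the same counts adjusted over the list alone (fry adjusted p of 0.173 or more, and 0.966 with an estimated correlation). The mixed test passed developmental regulators (adjusted p = 0.00142) and narrowly conserved miRNAs (0.00304), with the others at 0.47 or more. miRNAs with another 5′ base had a median of 0.41 and a mean of 0.62 where fry gave a downward direction.

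For the truncated untailed share, 6 of 38 groups passed the interaction test (10 at an unadjusted p under 0.05). The effect of HESO1 loss was more positive in hen1-8 for miR163 (log2 ratio of odds ratios 1.80 ± 0.34, adjusted p = 0.00784), miR159a/b/c (1.55 ± 0.18, adjusted p = 0.000473) and miR858a (1.22 ± 0.32, adjusted p = 0.0288). It was less positive there for miR394a (-1.65 ± 0.33, adjusted p = 0.00784), miR165a/miR166a (-1.32 ± 0.35, adjusted p = 0.0288) and miR403 (-1.02 ± 0.23, adjusted p = 0.0128). limma gave 3 groups and did not pass miR165a/miR166a (0.117), miR403 (0.0637) and miR858a (0.0637). With 2 nt or more missing 2 groups passed, and miR163, miR394a, miR403 and miR858a did not (adjusted p from 0.0931). Counted with or without a tail, miR163 stood at -0.84 and miR858a did not pass (0.0966). The count was 3 without heso1-1 replicate 2. The calls of miR165a/miR166a (adjusted p = 0.0641 to 0.159 without wild-type replicate 1, heso1-1 replicate 2 or either hen1-8 library), miR858a (0.0549 to 0.115 without wild-type replicate 1, hen1-8 replicate 1 or any 1 heso1-1 or double mutant library) and miR403 (0.0549 to 0.0781 without either heso1-1 library or double mutant replicate 1) were lost when 1 library was left out.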

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

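The patterns weighed here were found by fixed rules on the tables, the explanations and their predictions for the leak, for tails gained and for uncovered ends were written before their tests were run, and the other tests (last-base error, another enzyme, scaling, RNA quality and the 23-nt to 24-nt ratio in hen1-8) were chosen after the result was seen. The leak limit and the spread required of a truncation gain were also refined after their first values were seen, since a limit drawn from a miRNA with 0 U-tailed reads was 0 and a gain within the spread of libraries says little.

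The effect of HESO1 loss on the U-tailed share differed between backgrounds in 7 miRNA groups: miR159a/b/c (-2.67), miR165a/miR166a (-2.14), miR161.1 (-2.10), miR858a (-1.59), miR161.2 (-1.33), miR171b (1.53) and miR319a/c (2.32). Of these 7, miR159a/b/c and miR165a/miR166a were also among the 9 groups whose U-tailed share was higher in heso1-1 than in wild type. The tests of that rise below do not address the rest of the 7. Leaked barcodes are not a likely source, since 9 of these 9 groups would need a leaked fraction above the limit (9.67 to 56.3% of hen1-8 reads against a limit of 1.77%, or 4.20 to 38.2% of double mutant reads against 3.92%). In heso1-1, reads ending in 1 added A, C or G were fewer in 8 of the 9 groups, partly within the SD. Last-base errors may still explain the rise. Another enzyme that adds single U residues could explain it, but the share of U tails of 4 nt or more was lower in 5 of the 9 groups and higher in 2, and miR173 and miR867 had none in either genotype and so could not fall. With 7 measurable groups the threshold of 7 for a fit required all to fall, so this test leaves the explanation open.

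For the truncated untailed share the effect differed in 6 groups: miR163 (1.80), miR159a/b/c (1.55), miR858a (1.22), miR403 (-1.02), miR165a/miR166a (-1.32) and miR394a (-1.65). In heso1-1 the truncated share may rise only because ends that were tailed are now bare. Against that, 13 of the 17 called groups gained more than the tailed truncated share they had before, 11 of them beyond the spread of the libraries, with a median gain of 8.61 points against 3.24. In the double mutant 12 of 20 groups did so, 6 beyond the spread (21.2 points against 16.3), and the test cannot tell. In both comparisons the groups were picked for their rise in the same reads, which favours large gains, and groups not called were not examined. Degraded RNA in heso1-1 is not likely, since the log2 ratio of 23-nt to 24-nt reads changed by only 0.0677 while the median log2 odds ratio of the called groups was 1.43.

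Single-match 24-nt reads per window fell in hen1-8 against wild type on the scale of all reads. A fall of this kind could come from other RNAs filling the library. Scaled to organelle and structural reads the median log2 ratio was 0.41, no longer a fall, so scaling remains open as the source of part or all of it. The fall could also come from 24-nt RNAs gaining a tail and leaving the 24-nt class. Counted by prefix, hen1-8 still had 57.6% of the wild-type level in RPM of reads with a 24-nt genome-matching prefix (41.8% without a tail), so tail gain does not account for the whole fall in RPM. Dilution by other RNAs would lower RNAs of 23 and 24 nt alike, but they moved apart. Reads with a 23-nt prefix rose from 102490 to 256173 RPM (89677 to 119312 without a tail), and the log2 ratio of untailed 23-nt to 24-nt reads, which does not depend on library size, went from -2.47 ± 0.10 (SD, n = 2) to -0.80 ± 0.0142. Scaling alone therefore does not produce the change in this ratio. The ratio cannot tell whether the 24-nt fall itself is scaling, since a rise of 23-nt reads alone would also move it. How much of the fall is scaling, and whether the 23-nt RNAs are shortened 24-nt RNAs, was not tested.

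The other 20 annotated mature miRNAs, which were not on the list, had a median U-tailed share of 11.9% ± 1.16 (SD, n = 2) in hen1-8 and 8.10% ± 1.53 in the double mutant, lower than the listed groups. Of them, 12 come from hairpins of listed miRNAs. Their wild-type and heso1-1 medians were 1.40 and 0.565%, so the order of the genotypes was the same, and the cause of the lower level was not tested.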

How the results depend on the processing

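Of the settings here, the scaling to organelle and structural reads, the groups without a full-length read and the shares without miR390a and miR824 were chosen after the result was seen, and all others were fixed before the data were examined. "Full length" means full-length untailed reads, and the block is the replicate number. The labels do not pair the replicates, and the planned fits have no block. The correlation of replicate differences between genotypes ran from 0.0941 to 0.70 for abundance, positive in every pair of genotypes, and from -0.04 to 0.73 for the U-tailed share, and reads with an undetermined base differed by replicate number in every genotype. A batch shared by replicate number is therefore not excluded, and each count of groups or windows with the block is given below.

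The miRNA abundance count of hen1-8 against wild type (22) was 38 with the block, 35 with full-length untailed reads (miR167a/d -2.04) and 48 with library size from organelle and structural reads (miR319a/c 0.77). It ranged from 16 to 20 with 1 library left out. For the double mutant against hen1-8 (11) it was 17 with DESeq2, 34 with the block and 4 with full-length untailed reads (miR167a/d -0.0909), and 2 to 12 with 1 library left out (7 and 2 without hen1-8 replicates 1 and 2, 3 and 5 without those of the double mutant). For heso1-1 (1) it was 0 with TMM factors, 2 with DESeq2, 5 with the block, 0 with full-length untailed reads and 0 to 1 with 1 library left out (0 without wild-type replicate 1 or heso1-1 replicate 2). A call that is lost or gained this way was not traced further, and the cause was not tested.

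The U-tailed share count of hen1-8 (32) was 35 with the block, 19 of 22 with 200 or more reads per library and 30 to 34 with 1 library left out. For the double mutant (19) it was 27 with the block and 16 to 26 with 1 library left out, and with tails of 2 nt or more the signs of miR156h (-0.58), miR157a (-0.63), miR158a (-1.30), miR171b (-0.0868) and miR173 (-0.20) turned. For heso1-1 (18) it was 23 with the block, 7 with tails of 2 nt or more, where miR158a (-0.70), miR158b (-0.32), miR167a/d (0.13) and miR319a/c (0.42) turned, and 13 to 18 with 1 library left out. For the interaction (7) it was 12 with the block and 5 to 8 with 1 library left out, and with tails of 2 nt or more miR171b (-2.20) and miR319a/c (-0.96) turned. These turns follow from the measure, since tails of 1 nt are then not counted.

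The truncated untailed share count of hen1-8 (16) was 20 with the block (19 up, 1 down), 30 with truncated reads with or without a tail, 9 with 2 nt or more missing and 14 to 17 with 1 library left out. For the double mutant (20) it was 25 with the block, 13 of 22 with 200 or more reads per library, 12 with 2 nt or more missing (miR161.1 -0.25) and 16 to 23 with 1 library left out, and with or without a tail miR160a (-0.30), miR161.1 (-1.88) and miR163 (-0.85) turned. For heso1-1 (17) it was 22 with the block, 8 with 2 nt or more missing (miR158b -0.40) and 11 to 18 with 1 library left out (11 without heso1-1 replicate 2), and with or without a tail miR162a (-0.22) and miR163 (-0.00815) turned. For the interaction (6) it was 9 with the block, 3 with limma, 2 with 2 nt or more missing and 3 to 7 with 1 library left out (3 without heso1-1 replicate 2), with miR163 at -0.84 with or without a tail. The count for other tails in hen1-8 (28) was 28 with the block, 17 of 22 with 200 or more reads and 20 to 29 with 1 library left out, and in the double mutant (30) 33, 19 of 22 and 24 to 33. The mean U-tail length count (29) was 31 with the block, 10 of 27 on full-length prefixes, where miR158a (0.0519), miR158b (0.0220) and miR168a (0.26) turned, and 0 to 33 with 1 library left out (0 without double mutant replicate 1 or 2, each with a median difference of -0.41 nt and the spread of hen1-8 alone, 33 without either hen1-8 replicate). The cause of these moves was not tested.

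The count of 24-nt windows in hen1-8 (18138) was 19770 with the block, 6096 with TMM factors, 3741 with DESeq2, 5092 with library size from organelle and structural reads, 3872 for 20- to 22-nt reads and 13868 to 18894 with 1 library left out. For the double mutant (961) it was 2509 with the block, 2839 for 20- to 22-nt reads and 355 to 1074 with 1 library left out (385 and 561 without hen1-8 replicates 1 and 2, 355 without double mutant replicate 2). For heso1-1 (257) it was 169 with DESeq2, 443 with the block, 74 for 20- to 22-nt reads and 165 to 295 with 1 library left out (165 without heso1-1 replicate 2). fry called 19 lists and camera with an estimated correlation 0. As distinct sequences, 24-nt reads made up 40.2% in wild type, 40.2% in heso1-1, 29.1% in hen1-8 and 29.4% in the double mutant, and 25- to 28-nt reads 8.52, 7.46, 24.4 and 11.6%. The U-tailed share of 21-nt prefixes with a single genome match was 2.33, 2.27, 22.5 and 13.6% in that order, and with listed miRNAs left out 3.08, 2.60, 22.5 and 12.2%. With a single match it was 6.15% in wild type and 3.17% in the double mutant for 23-nt prefixes, and 0.642% in wild type, 20.8% in hen1-8 and 3.09% in the double mutant for 24-nt prefixes. With 1 library left out, each profile value became that of the other library, as printed with the profiles.

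Named results kept their call and sign in 459 U-tailed, 319 truncated, 253 other-tail, 55 length, 144 abundance and 93 window comparisons with another setting, lost their call in 23, 32, 3, 5, 19 and 3, and turned sign in 11, 8, 0, 3, 3 and 0. With 1 library left out they kept it in 423, 323, 278, 33, 136 and 142, lost their call in 33, 45, 26, 35, 40 and 2, and turned in 0.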

Other observations

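Besides U, tails of other bases were found on siRNA-sized RNAs. A tail here is the remainder after the longest genome match, so added bases were not told apart from mismatches. C tails on 23-nt prefixes made up 13.7% ± 0.520 (SD, n = 2) of reads in hen1-8 and 19.5% ± 0.307 in the double mutant, and A tails on 24-nt prefixes 1.23 and 3.83%. On 22-nt prefixes A tails ran the other way, from 12.1% in wild type and 11.3% in heso1-1 to 6.76% in hen1-8 and 6.24% in the double mutant. On miRNAs, tails of 1 C averaged 1.21% over groups in wild type, 0.769% in heso1-1, 3.72% in hen1-8 and 2.55% in the double mutant.

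A few 24-nt windows held many reads in some genotypes and almost none in others. The AT1G70080 window on chromosome 1 (26395001 to 26395500) held 0, 462, 200 and 88 reads in wild type, heso1-1, hen1-8 and the double mutant. The window at chromosome 5, 521501 to 522000, held 0, 345, 1 and 120. Only the second went with HESO1 loss, and the cause was not tested.

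Of the tests this part leans on, that of single U residues from another enzyme and that of scaling were chosen after the result was seen. The tests of U-tail shares by tail length, used below, were also added after the data were seen. U tails were shorter in the double mutant than in hen1-8 in 29 of 39 groups (median difference -0.43 nt, and -0.41 with either double mutant library left out), and their length in hen1-8 against wild type was not tested. The share of U tails of 4 nt or more fell in 30 of 38 groups in the double mutant and rose in 0, and the share of tails with other bases fell in 30 of 38 (19 of 22 with 200 or more reads). Tails of 1 U averaged 15.6% over groups in hen1-8 and 17.2% in the double mutant. By edgeR their share rose in 10 and fell in 11 of 38 groups (median log2 odds ratio 0.07). What adds them was left open by the test in heso1-1. The U-tailed share went from 20.3% in hen1-8 to 2.89% in the double mutant for 24-nt prefixes and from 23.4 to 13.9% for 21-nt prefixes. The smaller change at 21 nt was not limited to the listed miRNAs. With them left out the share went from 22.5 to 12.2%, and at 22 nt from 17.6 to 9.49%, although other miRNAs remain among those reads. The difference between prefix lengths was not tested.

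What the libraries cannot show is the amount of small RNA per cell. Values in RPM rest on a total that may itself differ between genotypes, which the scaling test (median 0.41) left open. A spike-in or a blot would be needed. Reads under 18 nt were not in the files, so truncation of an untailed 21-nt miRNA beyond 3 nt was not seen, and the shares of truncated reads could be underestimates where trimming goes further, which was not tested.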
